A study of Mus musculus with 61 samples.

How the data were processed

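The data were Tri-C libraries of mouse primary B cells. In Tri-C, crosslinked chromatin is digested and ligated, fragments that hold a chosen viewpoint are pulled down with a capture probe, and reads that join the viewpoint to 2 further fragments are counted as 3-way contacts. Per the labels, cells were crosslinked with formaldehyde, chromatin was cut with NlaIII, the DNA was sonicated, and each library was hybridized to its probe in 2 rounds. The authors aligned reads with Bowtie2 to the mouse genome build mm9. The Bowtie2 version, the handling of duplicate reads and the tool that called contacts are not given in the sources used here.

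The deposited unit is a signal. Each library has 1 upper-triangle matrix of 234 by 234 bins of 1 kb, in which each value stands for contacts of the viewpoint with a pair of bins. The matrices hold no coordinates, and positions are given here as kb from the first bin. Each deposited matrix sums to 300000. Tests on the values pointed to a second step that the labels do not state. In it, each value is a whole number of contacts, divided by a whole number for each of its bins and scaled to that sum. The fitted divisor differed between libraries in part of the bins. The fit took the smallest divisor that served about as well. The mean divisor was 3.21 in the library with 4039 recovered contacts and 4.83 in that with 89789. Whether the divisor used by the authors differed between libraries is therefore not known. The whole numbers were recovered per library from the values off the diagonal. The values on the diagonal did not enter each fit, but their share of whole values helped choose among candidate fits. They are thus not an independent check. The tolerance was 0.04 of a whole number, or 1.5 times the rounding error where that was larger. Of the off-diagonal values under 20 contacts 99.5% to 100% were whole. The fit was chosen to make these whole, so this share is not a test of it. Of the diagonal values under 20 contacts 70.2% to 100% were whole, and over 90% in 52 of 61 libraries. On simulated libraries, the total came back within 5% in 8 of 8. These were built with the same kind of division, so they test the recovery and not whether the division was made. Recovered contacts serve as depth and as an alternative measure only, since the divisor was inferred.

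Recovered depth ranged from 4039 to 89789 contacts per library, with a median of 20691. The 3 libraries without TPL in the TPL series had the lowest mean depth of any group, at 4039 to 6173 contacts each, and overlapped those with 1 h of TPL, at 5317 to 13698. The standard deviations given with each value are between libraries. For the IgG1 capture of the activation series they are between samples of summed clones, and leave out the spread between clones. Whether contacts are independent molecules is not given in the sources used here.

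Groups followed the labels, 23 in all, and 15 comparisons were made within the series of 1 probe. In the activation series of the IgG1 capture, the libraries that the labels call clone 1 and clone 2 were summed for each replicate number and time. Whether they come from separate cultures is not stated. This gave 2, 3 and 3 samples. In the Spt5 series the clones share only 1 replicate number among controls and 1 among depleted libraries, so the 9 libraries of the IgG1 capture were kept apart with clone as a term. If libraries of 1 number come from 1 culture, the 4 and 5 libraries are 3 and 4 distinct samples, and summing them was an alternative. The titles name 1 of the libraries at 0 h of each probe and clone in the activation series as replicates 1 and 3 together.

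A profile gives the percentage of contact ends in each of 24 blocks of 10 kb, the last of them 4 kb long. A table of block pairs gives the percentage of contacts for each of the 300 possible pairs of blocks. The list of elements, fixed before the data were examined, holds the sites of the other viewpoints and all pairs of them. A pair of a site with itself holds the contacts within its window, which also count toward the site. Each is a window of 11 kb around the bins that were empty at that probe, which lie at 31 kb for hs4, 85 kb for IgG2a, 142 kb for IgG1, 169 kb for IgG3 and 229 kb for Emu. The Emu window reaches the last bin and holds 10 kb. Features with a mean value of at least 100 of the 300000 were tested with limma 3.58.1 in R 4.3.3 on the log2 of the value plus 50. All libraries of a series and probe shared 1 fit. The prior variance followed a trend for block pairs and was constant for the profile. Benjamini-Hochberg adjustment ran over the 24 blocks, or over block pairs and elements together, at 0.05. Elements are also given adjusted over the list alone. Regions named in the text are the called elements and a set of called blocks and pairs. The set takes, among those with at least 10 recovered contacts in the higher group and 1 direction in all libraries, the 5 with the largest change each way. Elements that were not called are given as values. From these, the text gives examples and summarises the rest.

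The plan made before the data were examined was for raw counts. Since the values are a scaled signal, limma on log2 values took the place of the count model, and this choice was made after the unit was known.

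The crossing share is a measure of separation across the IgG1 viewpoint: of contacts with both ends outside its 11 kb window, the percentage with 1 end on each side. It was compared by exact two-sided permutation tests of libraries, within clone in the Spt5 series, with Benjamini-Hochberg adjustment over the 15 comparisons.

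The limma step was tested on simulated data with known changes, drawn from the values of 4 comparisons. Counts were drawn independently per pair with a dispersion of 0.05, which was not fitted to the spread of each series. Between real libraries of a group, chi-square per degree of freedom of pair counts lay between 3.40 and 19.0, above what counting alone gives. The rates below are too favourable where real libraries vary more than simulated ones. For the IgG1 capture at 72 h against 0 h, 66.7% of pairs changed 2-fold and 100% of pairs changed 4-fold were called, with 1 unchanged pair among 49 called. For Spt5 depletion these were 96.3% and 100%, with 3 of 53. For the Emu capture at 48 h they were 23.3% and 72.4%, with 4 of 32, and for TPL 1 h they were 6.90% and 37.9%, with 1 of 14. Changed pairs were drawn below 2% of contacts. A first run without that limit called more unchanged pairs. All values are shares of 1 total, so a change in a dominant pair moves the rest, but this was not tested as the cause.

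Alternatives were another filter, removal of contacts within 10 kb of the viewpoint, blocks of 5 kb for the profile or 20 kb for pairs, a window of 21 kb, removal of pairs under 20 kb apart, the replicate number as a block, each clone alone, clones summed or kept apart, and each library left out in turn. A pseudocount of 10, scaling by the median of ratios, limma's voom on recovered contacts, the crossing share in recovered contacts and thinning of all libraries to the lowest depth of their set were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 served for the rest.

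Libraries with 1 replicate number showed little shared deviation from their group means across conditions: mean correlations for a number in a set lay between -0.0830 and 0.133. Replicate 1 of IgG2a Spt5 (0.133) and replicate 2 of IgG3 (0.105) lay above the limit of 0.1, and the other numbers did not. With few libraries per group, the check could miss pairing. The numbers were not treated as pairs in the main fits. Within groups, Spearman correlations of block pairs lay between 0.534 and 0.875, and no 2 libraries were identical.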

Results

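Tri-C maps were made for 61 libraries of mouse primary B cells at the immunoglobulin heavy chain locus, Igh. Each map shows which pairs of places lie together with a viewpoint. The 5 viewpoints are named by their probes. These are hs4, an enhancer of the regulatory region beyond the last constant gene, then IgG2a, IgG1 and IgG3 at constant region genes, and Emu, the intronic enhancer near the J segments. Positions are kb from the first bin, since the maps carry no coordinates. The hs4 viewpoint lies at 31 kb, IgG2a 54 kb further, IgG1 57 kb beyond IgG2a, IgG3 27 kb beyond IgG1, and Emu 60 kb beyond IgG3. In the GRCm38.p6 annotation, which is not the build of the maps, the gene order is Igha, Ighe, Ighg2c, Ighg2b, Ighg1, Ighg3, Ighd, Ighm and the J segments. It has no Ighg2a, so the IgG2a site is named by its probe alone.

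The activation series followed cells at 0, 48 and 72 h in medium with LPS and IL4, a treatment that induces switching to IgG1. It had 2, 3 and 3 libraries at these times for the Emu probe and for the hs4 probe. The IgG1 probe had the same numbers for each of 2 clones, summed by replicate number. Titles of the activation, TPL and IgG3 sets name B18 AIDKO cells, AID being the deaminase that starts switch recombination. Titles of the Spt5 set do not name such cells, so they do not tell whether AID was absent there. The Spt5 series compared controls with cells activated for 62 h and depleted of Spt5, a transcription elongation factor, with 4HT in the last 32 h. It held 4 control and 5 depleted libraries from 2 clones for the IgG1 probe, and 2 and 3 for the IgG2a probe. Its titles read IgG1poolcapture where those of the activation series read IgG1capture. Both are called the IgG1 probe here, and whether they are the same is not stated. The labels give no activation time for these controls. The TPL series held 3 libraries each of cells activated for 72 h with no TPL, 1 h of TPL or 3 h of TPL at the Emu probe. Titles of the 3 libraries with no TPL end in _2, and those of the libraries with TPL do not. What this mark means is not stated. TPL is a compound that the labels do not spell out. The LPS series held 3 libraries at day 0 and 3 at day 3 for the IgG3 probe. Recovered depth was 4039 to 89789 contacts per library. Values are percentages of contact ends in a window or block, or of contacts for a pair, as mean ± SD.

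The first question was how contacts of the IgG1 region change as cells are activated for switching. Seen from IgG1, contacts at Emu rose from 2.31 ± 0.17% of ends (n = 2) at 0 h to 9.83 ± 1.17% (n = 3) at 48 h and 11 ± 1.0% (n = 3) at 72 h. Contacts at hs4 rose from 2.87 ± 0.31% to 5.65 ± 0.19% and 5.91 ± 0.23%. The IgG2a site between them fell from 4.51 ± 0.34% to 2.28 ± 0.20% and 1.99 ± 0.14%. The stretch from 60 to 130 kb as a whole held 33.2 ± 0.16% of ends at 0 h and 16.4 ± 0.45% at 72 h. The IgG3 site held 6.46 ± 0.09%, 7.02 ± 0.23% and 6.85 ± 0.44% and did not pass the test. Its log2 changes were 0.12 and 0.08 (adjusted p = 0.28 and 0.48, 5 of 5 and 4 of 5 samples).

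At 72 h the log2 change was 2.24 (SE 0.10) for Emu (limma adjusted p = 2.2e-20), 1.04 for hs4 (adjusted p = 1.4e-10) and -1.18 for IgG2a (adjusted p = 1.4e-09), each in 5 of 5 samples. At 48 h these were 2.07, 0.98 and -0.98, also in 5 of 5. Of the 24 blocks, 17 changed at 48 h, 7 up and 10 down, and 17 at 72 h, 8 up and 9 down. The largest rises at 72 h were in the last block, from 230 kb on (log2 2.34), and at 220-230 kb (2.03). Blocks at 20-30, 30-40 and 210-220 kb followed at 0.97, 0.97 and 0.96. The largest falls were at 100-110 kb (-1.24), 80-90 kb (-1.18), 90-100 kb (-1.12), 70-80 kb (-1.12) and 110-120 kb (-0.99).

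Contacts that joined IgG1 to a pair of other elements rose for some pairs and fell for others. Whether they changed beyond what the single sites imply was not tested. Contacts with both Emu and hs4 held 0.12 ± 0.028% at 0 h, 0.371 ± 0.112% at 48 h and 0.515 ± 0.113% at 72 h. The log2 changes were 1.47 and 1.95 (limma adjusted p = 8.9e-05 and 7.1e-07, 5 of 5 samples each). Contacts with Emu and IgG3 rose from 0.0878 ± 0.0240% to 0.416 ± 0.042% at 72 h, and those with IgG3 and IgG2a fell from 0.225 ± 0.033% to 0.0637 ± 0.0039%. Contacts within the Emu window rose from 1.31 ± 0.14% to 7.98 ± 1.04% and within the hs4 window from 1.51 ± 0.04% to 3.64 ± 0.14%. Contacts within the IgG2a window fell from 2.28 ± 0.05% to 1.11 ± 0.10%. In all, 10 of 14 elements and element pairs changed at each time over all pairs, and 10 adjusted over the list alone. Sites and the contacts within their windows overlap, so these are not separate changes.

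Among block pairs, limma called 36 up and 73 down at 48 h, and 41 up and 63 down at 72 h. Pairs of 220-230 kb with the last block rose most at 72 h, from 0.103% to 1.26% (log2 3.52). Pairs of 110-120 with 190-200 kb fell most, from 0.203% to 0.0231% (log2 -2.46). In clone 1 alone these falling pairs did not pass (log2 -1.32, adjusted p = 0.11 at 48 h and log2 -1.26, adjusted p = 0.12 at 72 h), nor did IgG3 with IgG2a at 72 h (log2 -1.26, adjusted p = 0.076). The balance of directions rests on the scaling. By the median of ratios, chosen after seeing the data, the median pair shifted by 0.35 and 0.27, and the pairs split 58 up and 33 down at 48 h and 59 up and 46 down at 72 h. That scaling also ended the call within the IgG2a window at 48 h (log2 -0.31, adjusted p = 0.17), as did clone 1 alone (log2 -0.47, adjusted p = 0.072). Without replicate 1 or 2 at 0 h, which leaves a lone sample there, 72 and 69 pairs were called at 48 h. The call for IgG3 with IgG2a at 48 h was lost without replicate 2 at 0 h (log2 -1.44, adjusted p = 0.053) and in clone 2 alone (log2 -1.51, adjusted p = 0.052). The call within the IgG3 window at 72 h (log2 0.28, adjusted p = 0.036, 5 of 5 samples) was lost without replicate 1 or 2 at 0 h (adjusted p = 0.14 and 0.13, log2 0.28 and 0.29). It was also lost without replicate 2 or 3 at 72 h (adjusted p = 0.11 and 0.12, log2 0.25 and 0.25), and by voom (log2 0.041, adjusted p = 0.76). It did not pass either with a replicate block, without contacts near the viewpoint or when thinned (log2 0.26, 0.22 and 0.27, adjusted p = 0.066, 0.088 and 0.065), in clone 1, in clone 2 or with clones apart (log2 0.24, 0.31 and 0.28, adjusted p = 0.23, 0.079 and 0.094).

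**Figure D1:**
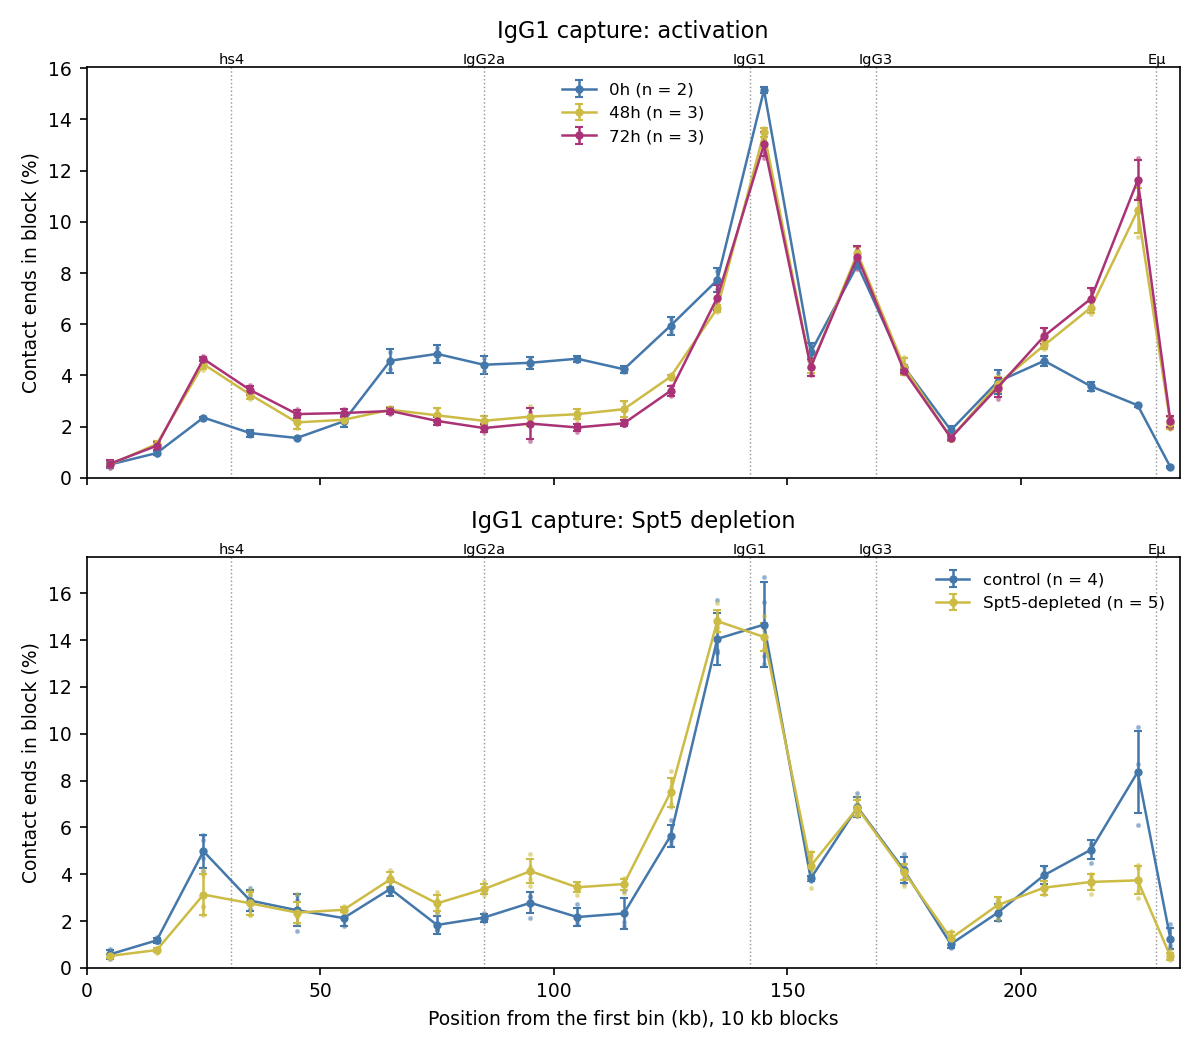
Percentage of contact ends (vertical axis) in 10 kb blocks along the map (horizontal axis, kb from the first bin) for the IgG1 probe, with activation in the upper panel and Spt5 depletion in the lower. Large points with lines are means, bars are SD, faint points are libraries (summed clones in the upper panel), and dotted lines mark the viewpoints; the block at 220-230 kb rises from 2.84% at 0 h to 11.6% at 72 h and stands at 8.37% in controls and 3.74% in depleted cells.

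The Emu probe views the same contact from the other end. Contacts of Emu with the IgG1 site rose from 2.18 ± 0.76% (n = 2) at 0 h to 6.23 ± 0.09% (n = 3) at 48 h and 7.81 ± 0.13% (n = 3) at 72 h. The log2 changes were 1.56 and 1.88 (limma adjusted p = 5.2e-05 and 4.5e-06, 5 of 5 libraries each). Contacts within the IgG1 window rose from 1.27 ± 0.25% to 4.40 ± 0.25% and 5.67 ± 0.54%. Contacts of Emu with IgG1 and hs4 together held 0.0875 ± 0.124%, 0.358 ± 0.087% and 0.522 ± 0.279%. This passed at 72 h (log2 3.12, adjusted p = 0.028, 5 of 5) and not at 48 h (log2 2.70, adjusted p = 0.068, 0.029 adjusted over the list alone, 5 of 5). The hs4 site itself held 7.65 ± 0.21%, 9.49 ± 0.77% and 8.65 ± 0.98% and did not pass.

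Blocks at 140-150 and 130-140 kb rose at both times, by 1.41 and 0.93 at 48 h and 1.70 and 1.68 at 72 h on the log2 scale. The block at 210-220 kb changed by -1.13 and -1.15, and the block at 60-70 kb by -1.46 and -1.0. The fall at 60-70 kb at 72 h lost its call by voom on recovered contacts (log2 -0.24, adjusted p = 0.42). Limma called 5 blocks up and 7 down at 48 h, and 2 up and 3 down at 72 h. By the median of ratios, which shifted the median block by 0.40 and 0.18, these were 6 up and 4 down, and 3 up and 2 down. Among pairs it called 9 up and 6 down at 48 h (14 and 4 by the median of ratios, a shift of 0.23) and 14 up and 4 down at 72 h (14 and 4, a shift of 0.12). By voom, 4 pairs and 10 blocks were called at 72 h. Pairs of 140-150 with 220-230 kb rose from 0.129% to 0.914% at 48 h (log2 3.71, adjusted p = 0.016, 5 of 5). That call was lost without replicate 1 at 0 h or replicate 2 at 48 h (log2 1.69 and 3.72, adjusted p = 0.078 and 0.066) and was larger without replicate 2 at 0 h (log2 5.73, adjusted p = 5.8e-07). Of the 14 elements and pairs, 2 passed at 48 h and 3 at 72 h over all pairs, and 6 and 3 adjusted over the list alone. At 48 h the list alone added IgG1 with hs4, IgG2a (log2 -0.95, adjusted p = 0.10, 0.042 adjusted over the list alone, 5 of 5), IgG3 with IgG2a (log2 -3.07, adjusted p = 0.11, 0.042 adjusted over the list alone, 5 of 5) and contacts within the hs4 window (log2 0.43, adjusted p = 0.11, 0.042 adjusted over the list alone, 5 of 5). The last passed without contacts near the viewpoint (log2 0.80, adjusted p = 7.2e-04) and by voom (log2 0.47, adjusted p = 0.0065).

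Single libraries weighed on the counts of the Emu probe. At 48 h, 7 and 7 blocks and 8 and 30 pairs were called without replicate 1 or 2 at 0 h. Without replicate 2 or 3 at 48 h, 6 and 7 blocks and 2 and 6 pairs were called. At 72 h, 5, 6 and 6 pairs were called without replicate 1, 2 or 3 at 72 h. The call for IgG1 with hs4 at 72 h was lost without replicate 1 at 0 h (log2 1.36, adjusted p = 0.28) and without replicate 1, 2 or 3 at 72 h (log2 3.16, 2.73 and 3.48, adjusted p = 0.11, 0.13 and 0.060). It was also lost by voom (log2 3.42, adjusted p = 0.14) and when thinned (log2 2.97, adjusted p = 0.061). It grew without replicate 2 at 0 h (log2 4.88, adjusted p = 8.1e-05). At 48 h it was gained without replicate 2 at 0 h (log2 4.46, adjusted p = 3.1e-04) and shrank without replicate 1 at 0 h (log2 0.94, adjusted p = 0.43). At 48 h it was also gained without contacts near the viewpoint, in 20 kb blocks and by the median of ratios (log2 3.36, 2.70 and 2.89, adjusted p = 0.010, 0.035 and 0.026). The IgG2a site also passed at 48 h without replicate 2 at 0 h (log2 -1.23, adjusted p = 0.041).

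From hs4, the largest rises were at 130-140 and 120-130 kb. The block at 130-140 kb rose from 1.78 ± 0.09% (n = 2) to 4.66 ± 0.37% (n = 3) and 5.53 ± 0.43% (n = 3), log2 1.38 and 1.62. The block at 120-130 kb rose from 2.67 ± 0.32% to 5.75 ± 0.71% and 5.92 ± 0.38%, and the block at 110-120 kb rose by 0.77 on the log2 scale at both times. Nearer hs4, contacts at 40-50 kb fell from 8.96 ± 0.05% to 4.99 ± 0.48% and 6.14 ± 0.14%, and those at 50-60 and 60-70 kb fell as well. Without replicate 1 at 0 h the last 2 calls were lost at 48 h (log2 -0.49 and -0.40, adjusted p = 0.065 and 0.096) and at 72 h (log2 -0.41 and -0.39, adjusted p = 0.098 and 0.098), and 60-70 kb did not pass at 48 h with a replicate block (log2 -0.46, adjusted p = 0.055). At 72 h the block that holds the IgG1 viewpoint, 140-150 kb, also rose (log2 0.72, adjusted p = 0.0046, 5 of 5). Blocks away from IgG1 changed too. At 48 h 10-20 kb (log2 0.96, adjusted p = 0.0027, 5 of 5) rose, and at 72 h 0-10 kb (log2 1.11, adjusted p = 0.046, 5 of 5) rose while 200-210 kb (log2 -0.78, adjusted p = 0.0062, 5 of 5) and 170-180 kb (log2 -0.62, adjusted p = 0.0054, 5 of 5) fell. The call at 0-10 kb was lost without replicate 1 or 2 at 0 h or replicate 2 or 3 at 72 h (log2 0.86, 1.37, 1.12 and 0.86, adjusted p = 0.26, 0.061, 0.098 and 0.12), and that at 170-180 kb by voom (log2 -0.38, adjusted p = 0.093). The IgG1 site held 2.01 ± 0.43% at 0 h and 3.62 ± 0.18% at 72 h (log2 0.86, limma adjusted p = 0.014, 5 of 5). The Emu site held 5.24 ± 0.81%, 4.99 ± 0.60% and 5.22 ± 1.08% and did not pass. Contacts of hs4 with Emu and IgG1 together did not pass at either time. Their log2 change was -0.39 at 48 h (limma adjusted p = 0.80). At 72 h it lay between 0.39 and 1.25 with 1 library left out in turn.

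Limma called 6 blocks up and 3 down at 48 h, and 6 up and 5 down at 72 h. Among 255 pairs it called 5 up and 3 down at 48 h and 7 up and none down at 72 h. By the median of ratios, a shift of 0.26, the pairs at 48 h were 10 up and 2 down, and by voom 21 and 23 pairs were called. Contacts of hs4 with 20-30 and 130-140 kb rose from 0.196% to 0.681% and 0.995% (log2 1.72 and 2.19, adjusted p = 0.013 and 8.8e-04, 5 of 5 each). The call at 48 h was lost without replicate 1 at 0 h (log2 1.54, adjusted p = 0.086). Of 14 elements and pairs, IgG1 was the 1 called at 72 h, over all pairs and adjusted over the list alone. At 48 h limma called 0 of them both ways. That IgG1 call was lost without replicate 2 at 0 h (log2 0.64, adjusted p = 0.20), without replicate 1 or 2 at 72 h (log2 0.87 and 0.82, adjusted p = 0.089 and 0.093), without contacts near the viewpoint (log2 0.71, adjusted p = 0.10) and with a replicate block (log2 0.82, adjusted p = 0.065). Without replicate 1 at 0 h, 5 blocks and 4 pairs were called at 48 h. Without replicate 1 at 72 h, 4 pairs were called at 72 h.

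**Figure D2:**
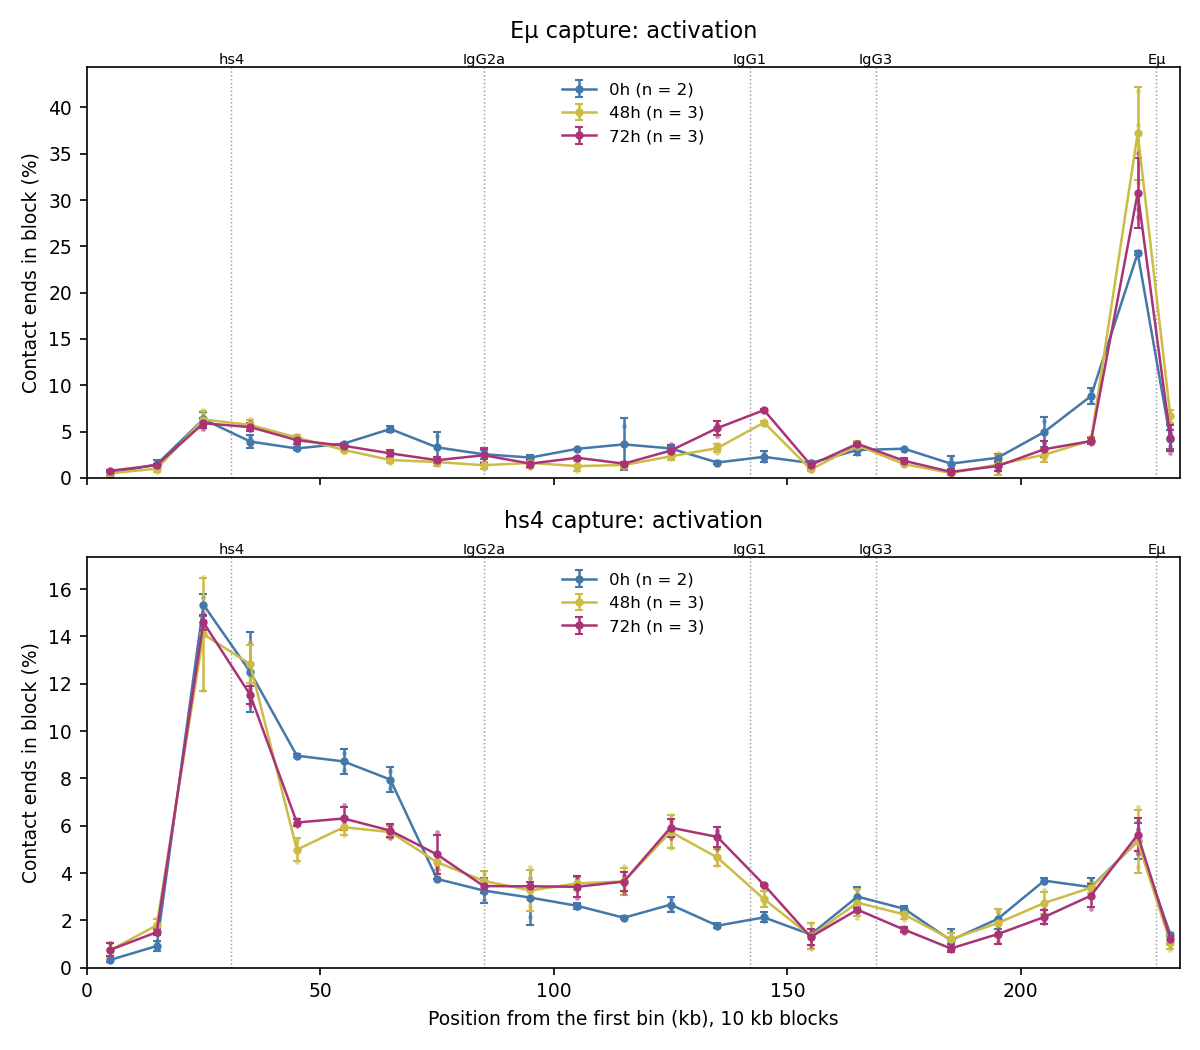
Percentage of contact ends (vertical axis) in 10 kb blocks along the map (horizontal axis, kb from the first bin) for the Emu probe in the upper panel and the hs4 probe in the lower, at 0, 48 and 72 h. Large points with lines are means, bars are SD and faint points are libraries; from hs4, the block at 130-140 kb goes from 1.78% at 0 h to 5.53% at 72 h, and from Emu, the block at 140-150 kb goes from 2.28% to 7.32%.

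Between 48 and 72 h, limma called 0 blocks and 0 pairs for each of the 3 probes. At unadjusted p under 0.05 there were 6 blocks and 16 pairs for Emu, 3 and 19 for hs4, and 5 and 20 for IgG1. Voom on recovered contacts called 4 blocks and 1 pair for Emu, 1 and 1 for hs4, and 4 blocks and 0 pairs for IgG1. Contacts within the IgG2a window, seen from Emu, held 0.837 ± 0.196% and 1.93 ± 0.64% (log2 1.16, adjusted p = 0.30, 0.045 adjusted over the list alone, 6 of 6 libraries). Without replicate 1 at 48 h, 1 block was called for Emu, 1 block for hs4 and 2 pairs for IgG1. Without replicate 3 at 72 h, 1 block was called for Emu. For IgG1, 2 blocks were called without replicate 2 at 48 h and 1 without replicate 1 at 72 h.

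The series title names a boundary in the locus, and the crossing share asked whether contacts across the IgG1 viewpoint became rarer. Seen from hs4, it was 18.7 ± 0.71% at 0 h (n = 2), 11.3 ± 2.4% at 48 h (n = 3) and 13.1 ± 0.74% at 72 h (n = 3). Seen from IgG1, it was 15.8 ± 0.01%, 11.4 ± 1.9% and 12.3 ± 0.56%, and from Emu 12.4 ± 0.21%, 8.89 ± 1.98% and 9.68 ± 1.79%. For the IgG1 probe it went from 16.7% at 0 h to 14.7% at 72 h in clone 1, and from 14.9% to 9.93% in clone 2. The SD for this probe is between samples of summed clones. At 0 h its single libraries held 16.3% to 17.2% in clone 1 and 14.4% to 15.4% in clone 2. Those of clone 1 at 72 h held 14.3% to 14.9%, which overlaps clone 2 at 0 h. The exact two-sided permutation p against 0 h was 0.1 and 0.1 for hs4, 0.2 and 0.1 for IgG1, and 0.2 and 0.2 for Emu. The smallest p this design allows is 0.1, so none can pass, and the lowest after adjustment over the 15 comparisons was 0.29. For the Emu probe the direction rested on close pairs. Without pairs under 20 kb apart, its share was higher than at 0 h by 8.13 points at 48 h and 2.37 points at 72 h. Between 48 and 72 h the exact permutation p was 0.8, 0.3 and 0.5 for Emu, hs4 and IgG1. The Emu difference of 0.795 points turned to -0.0372 without replicate 3 at 48 h.

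**Figure D3:**
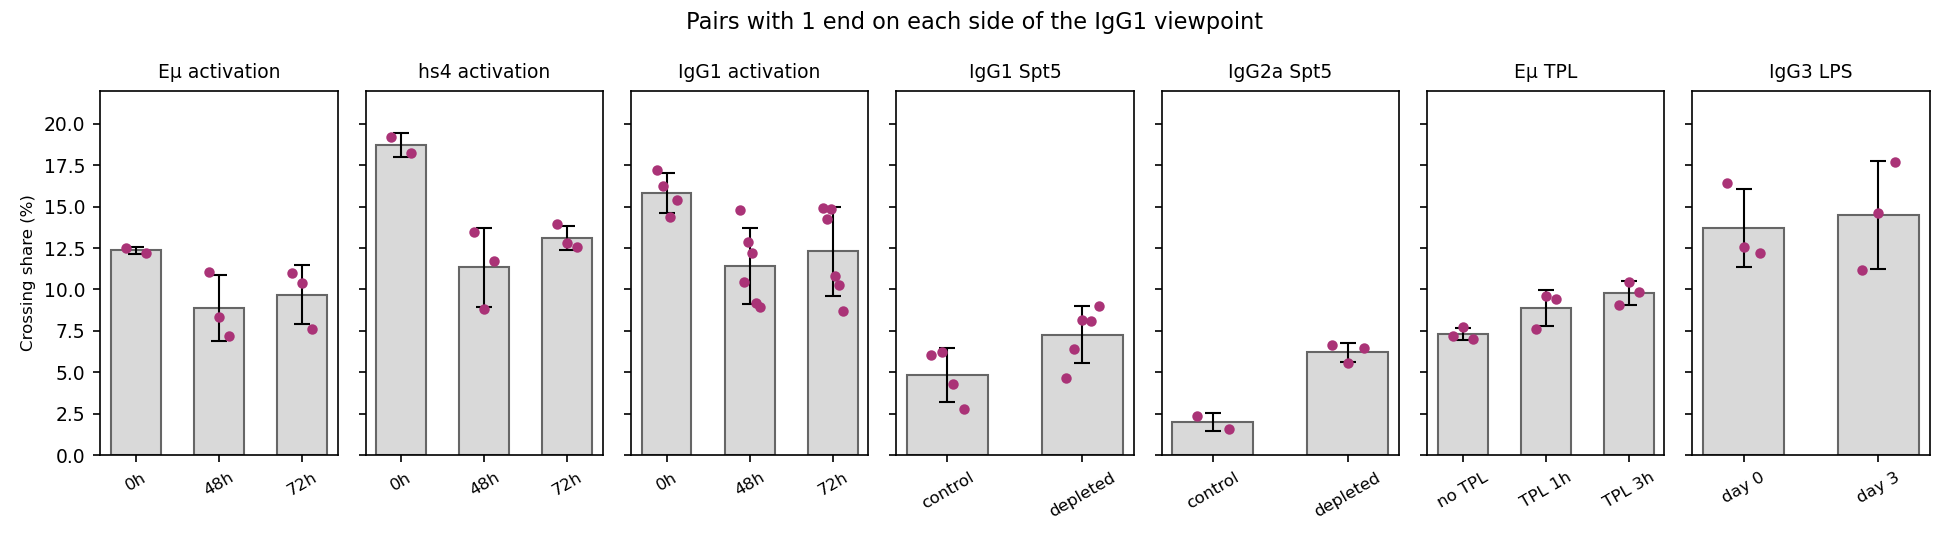
Percentage of contacts outside the IgG1 window that join its sides (vertical axis) in each series and probe, by group. Bars are means over libraries, error bars SD and points libraries, with the clones of the IgG1 probe kept apart; in the hs4 panel both libraries at 0 h lie above the 6 later ones, and in the IgG2a panel the 3 depleted libraries lie above both controls.

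The Spt5 series asked whether the contacts of activated cells depend on this elongation factor. Seen from IgG1, contacts at Emu fell from 7.34 ± 1.82% in controls (n = 4) to 2.86 ± 0.65% after depletion (n = 5). Contacts at the IgG2a site rose from 2.36 ± 0.17% to 3.68 ± 0.21%. Contacts at hs4 fell from 6.00 ± 0.51% to 4.77 ± 1.23%. Contacts with both Emu and hs4 held 0.188 ± 0.174% and 0.151 ± 0.035% and did not pass (log2 0.21, limma adjusted p = 0.78, 3 of 9 libraries). The means fell while the log2 change, taken within clones, was above 0. Control clone 1 replicate 1 alone held 0.434% for Emu with hs4. The IgG3 site held 6.18 ± 0.53% and 6.07 ± 0.35% and did not pass.

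The log2 changes were -1.33 (SE 0.147) for Emu (limma adjusted p = 2.4e-08, 9 of 9 libraries), 0.65 for IgG2a (adjusted p = 3.4e-04, 9 of 9) and -0.32 for hs4 (adjusted p = 0.043, 7 of 9). Contacts within the Emu window changed by -1.54, within the IgG2a window by 0.49 (adjusted p = 0.017, 9 of 9) and within the hs4 window by -0.42 (adjusted p = 0.034, 7 of 9). Limma called 6 of 24 blocks up and 5 down, 18 of 180 pairs up and 7 down, and 6 of 13 elements and pairs, over all pairs and adjusted over the list alone. The called elements were the Emu, IgG2a and hs4 sites and the contacts within their windows, which overlap. Blocks from 70 to 120 kb rose, most at 100-110 kb (0.68) and 110-120 kb (0.67). The last block (-1.27) and the blocks at 220-230 kb (-1.13), 20-30 kb (-0.67), 10-20 kb (-0.62) and 210-220 kb (-0.47) fell. Pairs of 60-70 with 160-170 kb rose most, from 0.0173% to 0.0863% (log2 1.78, adjusted p = 0.016, 9 of 9), a call lost without control clone 2 replicate 2 or depleted clone 2 replicate 1 (log2 1.52 and 1.65, adjusted p = 0.055 and 0.053) and in clone 1 alone (log2 1.24, adjusted p = 0.66). Pairs of 220-230 kb with the last block fell most, from 0.633% to 0.168% (log2 -1.81, adjusted p = 2.9e-04, 9 of 9).

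The rise of pairs rests on the scaling. The median of ratios, which shifted the median pair by -0.33, gave 3 pairs up and 10 down. It ended the calls at IgG2a (log2 0.25, adjusted p = 0.62), within the IgG2a window (log2 0.10, adjusted p = 0.87), at hs4 (log2 -0.72, adjusted p = 0.17) and within the hs4 window (log2 -0.81, adjusted p = 0.14). With replicate numbers as a block, though they showed little pairing of libraries, limma called 3 pairs. The calls then ended at hs4, within the hs4 window and within the IgG2a window (log2 -0.33, -0.46 and 0.38, adjusted p = 0.17, 0.065 and 0.31), and for 60-70 with 160-170 kb and 220-230 kb with the last block (log2 2.14 and -1.37, adjusted p = 0.062 and 0.055). The call at hs4 was also lost without a filter, without contacts near the viewpoint, in 20 kb blocks, with a pseudocount of 10 and with clones summed (log2 -0.32, -0.32, -0.32, -0.32 and -0.33, adjusted p = 0.087, 0.062, 0.054, 0.053 and 0.057), and that within the hs4 window without a filter (log2 -0.42, adjusted p = 0.069). Libraries of 1 replicate number in both clones are not stated to be separate cultures, and with them summed to 3 and 4 samples 11 blocks and 25 pairs were called. In clone 1 alone limma called 0 blocks and 3 pairs, the IgG2a change was 0.64 (adjusted p = 0.19), the change within the IgG2a window 0.62 (adjusted p = 0.31) and the hs4 change -0.02 (adjusted p = 0.97). There the change within the hs4 window turned to 0.059 (adjusted p = 0.97). In clone 2 alone it called 75 pairs, and contacts with Emu and hs4 passed (log2 1.12, adjusted p = 0.033). Called pairs numbered 12, 9 and 8 without control clone 1 replicate 1, clone 2 replicate 1 or clone 2 replicate 2. They numbered 50, 11, 11 and 10 without depleted clone 1 replicate 3 or clone 2 replicate 1, 2 or 3. The call at hs4 was lost without each of those 3 controls (log2 -0.34, -0.23 and -0.29, adjusted p = 0.070, 0.30 and 0.18) and without each depleted library of clone 2 (log2 -0.34, -0.28 and -0.28, adjusted p = 0.067, 0.16 and 0.13). The call within the hs4 window was lost without the same controls (log2 -0.46, -0.31 and -0.32, adjusted p = 0.064, 0.26 and 0.23) and the same depleted libraries (log2 -0.43, -0.34 and -0.38, adjusted p = 0.053, 0.14 and 0.073). That within the IgG2a window was lost without depleted clone 1 replicate 4 or clone 2 replicate 3 (log2 0.43 and 0.47, adjusted p = 0.056 and 0.060). The change with Emu and hs4 turned to -0.43 without control clone 2 replicate 2 (adjusted p = 0.57).

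The crossing share was 4.85 ± 1.61% in controls (n = 4) and 7.29 ± 1.72% after depletion (n = 5), a difference within clones of 2.15 points (exact two-sided permutation p = 0.12, smallest possible 0.017). It was -0.58 points in clone 1 and 4.87 in clone 2. The exact permutation p for the difference between clones was 0.05, which is not under the threshold. Without depleted clone 1 replicate 3 the difference was 2.58 points (exact permutation p = 0.033). The number of 1 kb bin pairs with any contact fell in clone 1 and rose in clone 2, as the crossing share did. In clone 1 it was 3252 and 3434 in controls, and 1841 and 2716 after depletion. In clone 2 it was 2492 and 1701 in controls, and 4795, 4465 and 3862 after depletion. Whether this accounts for the crossing share was not tested.

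From the IgG2a probe, contacts within the viewpoint's own block, 80-90 kb, fell from 23.7 ± 2.4% in controls (n = 2) to 17.5 ± 0.33% after Spt5 depletion (n = 3). The log2 change was -0.43 (limma adjusted p = 0.0020, 5 of 5 libraries). Contacts with 70-80 and 190-200 kb, listed at 0 in both controls, held 0.209 ± 0.137% after depletion (adjusted p = 0.048, higher in 3 of 3 depleted libraries). The Emu site held 1.40 ± 0.10% and 1.04 ± 0.20%, IgG1 1.95 ± 0.37% and 2.62 ± 0.35%, and hs4 2.27 ± 0.46% and 2.36 ± 0.40%. Limma called 0 of 11 elements and pairs, over all pairs and adjusted over the list alone. It called 0 of 24 blocks, with 3 at unadjusted p under 0.05 and 2 by voom, and 2 pairs, with 43 at unadjusted p under 0.05 and 1 by voom. The crossing share at IgG1 was 2.00 ± 0.55% and 6.22 ± 0.57%, a difference of 4.21 points (exact two-sided permutation p = 0.1, the smallest possible). The 1 kb bin pairs with any contact numbered 860 and 639 in controls, and 1581, 1643 and 1547 after depletion. Whether this accounts for the rises was not tested. Without control replicate 1 or 2, 17 and 9 pairs were called, and without depleted replicate 1, 2 or 3, 0, 1 and 0 by limma. The median of ratios, a shift of -0.26, left 1 pair, the fall, and without contacts near the viewpoint limma called 0 pairs. The rise was lost without depleted replicate 1, 2 or 3 (log2 3.82, 3.84 and 3.13, adjusted p = 0.22, 0.077 and 0.29), and the fall without depleted replicate 1 or 3 (log2 -0.45 and -0.43, adjusted p = 0.17 and 0.29). The rise also lost its call by voom and when thinned (log2 4.60 and 3.6, adjusted p = 0.18 and 0.063), with a replicate block (log2 3.13, adjusted p = 0.12) and without a filter (adjusted p = 0.091).

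The TPL series asked whether contacts of Emu change with a treatment in the last hours. Contacts of Emu with the IgG1 site rose from 6.44 ± 1.05% with no TPL to 14.2 ± 3.0% after 1 h, and stood at 10.1 ± 0.95% after 3 h (n = 3 each). The log2 change at 1 h was 1.13 (SE 0.175, limma adjusted p = 1.2e-04, 6 of 6 libraries). At 3 h it was 0.65 and did not pass (adjusted p = 0.058, 0.0056 adjusted over the list alone, 6 of 6). Contacts within the IgG1 window rose from 5.06 ± 1.21% to 10 ± 2.6% at 1 h (log2 0.98, adjusted p = 0.011, 6 of 6). The hs4 site held 9.48 ± 0.91%, 13.3 ± 2.1% and 14.1 ± 1.4% (log2 0.49 and 0.57, adjusted p = 0.092 and 0.058, 0.011 and 0.0056 adjusted over the list alone, 6 of 6 each). Emu with IgG1 and hs4 together held 0.427 ± 0.370%, 1.42 ± 0.32% and 1.32 ± 0.54% (log2 2.86 and 2.72, adjusted p = 0.11 and 0.12, 0.014 and 0.024 adjusted over the list alone, 6 of 6 each). Without no TPL replicate 2 these were 1.10 and 0.95 (adjusted p = 0.32 and 0.37). Contacts within 220-230 kb, a block that holds part of the viewpoint, fell from 18.7 ± 2.3% to 12.3 ± 0.67% at 1 h (log2 -0.60, adjusted p = 0.011, 6 of 6). Pairs of 20-30 with 140-150 kb rose from 0.0664 ± 0.0203% to 0.815 ± 0.122% (log2 3.34, adjusted p = 0.030, 6 of 6).

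Of 13 elements and pairs, 2 passed over all pairs at 1 h, and limma called 0 at 3 h and 0 between 1 and 3 h. Adjusted over the list alone these were 5, 5 and 0. They include contacts within the hs4 window at 1 h (log2 0.53, adjusted p = 0.11, 0.014 adjusted over the list alone, 6 of 6) and at 3 h (log2 0.63, adjusted p = 0.058, 0.0056 adjusted over the list alone, 6 of 6), and IgG1 with IgG2a at 3 h (log2 3.19, adjusted p = 0.19, 0.039 adjusted over the list alone, 6 of 6). By voom contacts within the hs4 window passed at 1 h (log2 0.45, adjusted p = 0.0084). Limma called 0 of 24 blocks in each of the 3 comparisons, with 8, 6 and 2 at unadjusted p under 0.05 and 6, 1 and 0 by voom. It called 2 pairs at 1 h, 0 at 3 h and 0 between 1 and 3 h, with 19, 24 and 10 at unadjusted p under 0.05 and 4, 0 and 3 by voom. The crossing share was 7.32 ± 0.36%, 8.88 ± 1.10% and 9.79 ± 0.71%. The exact two-sided permutation p was 0.2, 0.1 and 0.4 for 1 h, 3 h and 3 h against 1 h (n = 3 each), and in recovered contacts the change was -1.40 points at 1 h and -0.0229 at 3 h.

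The depth of the TPL series was 4039 to 13698 contacts per library, and in simulated data at this size 6.90% of 2-fold changes of a pair were called. The call within the IgG1 window was lost without 1 h replicate 1 or 3 (log2 0.82 and 0.92, adjusted p = 0.23 and 0.16) or no TPL replicate 2 or 3 (log2 0.87 and 0.90, adjusted p = 0.066 and 0.091). It was also lost by the median of ratios (log2 0.72, adjusted p = 0.24), by voom (log2 0.61, adjusted p = 0.26) and when thinned (log2 0.80, adjusted p = 0.15). Limma called 0 pairs at 1 h without 1 h replicate 1 or 3 or no TPL replicate 3, and 4 and 5 without no TPL replicate 1 or 2. It called 5 blocks without 1 h replicate 2 and 3 without no TPL replicate 1. The hs4 site passed at 1 h without 1 h replicate 2 (log2 0.58, adjusted p = 0.030), and IgG1 with hs4 without no TPL replicate 1 (log2 3.75, adjusted p = 0.029) and by voom (log2 3.45, adjusted p = 0.021). By the median of ratios, a shift of -0.14, 1 pair was called at 1 h, the fall. When thinned, the rise of 20-30 with 140-150 kb lost its call (log2 3.23, adjusted p = 0.15), as it did by the median of ratios and with a replicate block (log2 3.12 and 3.34, adjusted p = 0.073 and 0.060). It was also lost without 1 h replicate 1, 2 or 3 or no TPL replicate 3 (log2 3.36, 3.43, 3.23 and 3.20, adjusted p = 0.18, 0.061, 0.21 and 0.091). The fall within 220-230 kb was lost without 1 h replicate 1 or 3 or no TPL replicate 3 (log2 -0.60, -0.55 and -0.50, adjusted p = 0.086, 0.13 and 0.12).

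**Figure D4:**
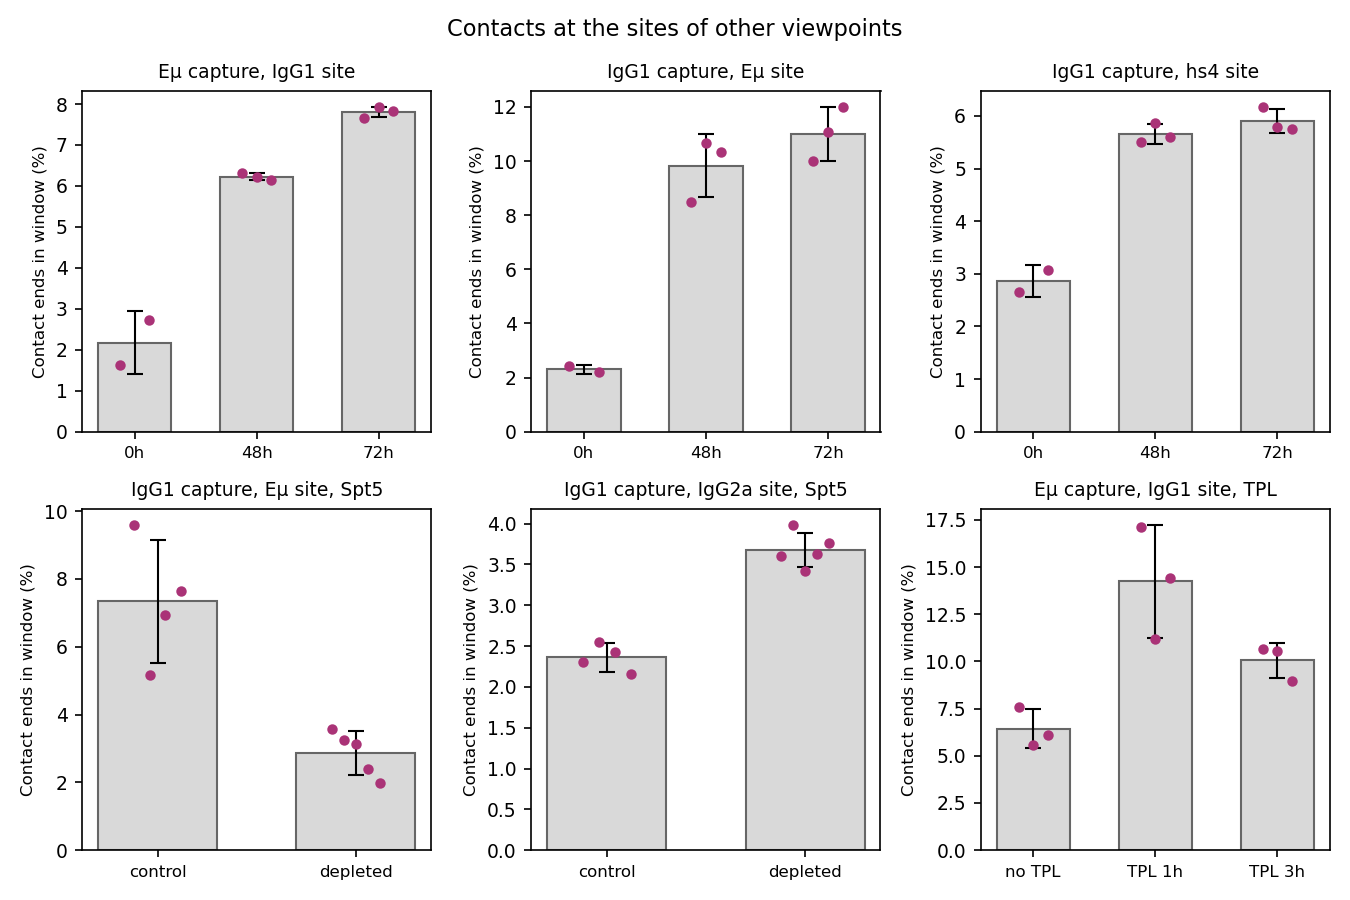
Percentage of contact ends in the window of another viewpoint (vertical axis) by group, for the probe and site named above each panel. Bars are means, error bars SD and points libraries (summed clones for IgG1 activation); IgG1 contacts of Emu are highest after 1 h of TPL at 14.2%, and Emu contacts of IgG1 are 7.34% in controls and 2.86% after Spt5 depletion.

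The LPS series asked what changes at IgG3, a gene to which LPS alone induces switching. Contacts of IgG3 with the block at 20-30 kb, next to hs4, rose from 2.70 ± 0.33% at day 0 (n = 3) to 4.05 ± 0.08% at day 3 (n = 3), log2 0.59 (limma adjusted p = 0.041, 6 of 6 libraries). Contacts with 90-100 and 190-200 kb fell from 0.272 ± 0.095% to 0.0180 ± 0.0184% (log2 -3.16, adjusted p = 0.049, 6 of 6). The hs4 window held 3.68 ± 0.75% and 5.57 ± 0.45% (log2 0.61, adjusted p = 0.081, 0.0059 adjusted over the list alone, 6 of 6). IgG3 with both Emu and hs4 held 0.157 ± 0.034% and 0.585 ± 0.145% (log2 1.78, adjusted p = 0.081, 0.0059 adjusted over the list alone, 6 of 6). The Emu site held 4.10 ± 0.73% and 4.63 ± 1.29% and IgG1 4.36 ± 0.70% and 3.52 ± 0.25%, and neither passed.

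These were the 1 of 24 blocks and the 1 pair called, with 3 and 17 at unadjusted p under 0.05 and 3 and 3 by voom. Limma called 0 of 13 elements and pairs over all pairs and 5 adjusted over the list alone. Besides the hs4 window and Emu with hs4 above, these were rises within the hs4 window (log2 0.81, adjusted p = 0.051, 0.0055 adjusted over the list alone, 6 of 6) and of Emu with IgG1, from 0.0232 ± 0.0102% to 0.15 ± 0.0865% (log2 1.98, adjusted p = 0.30, 0.033 adjusted over the list alone, 6 of 6). The fifth was a fall within the IgG1 window, from 3.03 ± 0.299% to 2.11 ± 0.15% (log2 -0.52, adjusted p = 0.30, 0.033 adjusted over the list alone, 6 of 6). The block lost its call without day 0 replicate 2 or 3 (log2 0.50 and 0.60, adjusted p = 0.091 and 0.14) or day 3 replicate 1, 2 or 3 (log2 0.58, 0.58 and 0.61, adjusted p = 0.11, 0.11 and 0.092). Limma called 0 blocks in each of these cases but the one without day 3 replicate 2. The block also lost it without contacts near the viewpoint (log2 0.63, adjusted p = 0.057) and when thinned (log2 0.53, adjusted p = 0.067), and 0 blocks of 5 kb were called by limma. Limma called 0 pairs without day 0 replicate 1, 2 or 3 or day 3 replicate 2 (the pair at log2 -2.92, -3.41, -3.14 and -3.55, adjusted p = 0.29, 0.17, 0.23 and 0.070), and 2 without day 3 replicate 3. The pair lost its call by voom (log2 -2.57, adjusted p = 0.52) and when thinned (log2 -3.06, adjusted p = 0.051), without a filter (adjusted p = 0.072) and with a pseudocount of 10 (log2 -4.24, adjusted p = 0.11). The hs4 window passed without day 3 replicate 1 (log2 0.65, adjusted p = 0.042). The hs4 window, contacts within it and IgG3 with Emu and hs4 passed with a replicate block (log2 0.61, 0.81 and 1.78, adjusted p = 0.045, 0.031 and 0.045) and without contacts near the viewpoint (log2 0.74, 0.92 and 1.93, adjusted p = 0.014, 0.0093 and 0.014). The last 2 also passed in 20 kb blocks (adjusted p = 0.037 each). The crossing share at IgG1 was 13.7 ± 2.3% and 14.5 ± 3.2% (exact two-sided permutation p = 0.8, n = 3 each, smallest possible 0.1), and the difference of 0.772 points turned to -0.815 without day 3 replicate 3.

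Untreated cells at 72 h were mapped from Emu in both the activation and the TPL series (n = 3 each). Between them limma called 0 of 24 blocks and 0 pairs, with 5 and 16 at unadjusted p under 0.05 and 2 and 1 by voom. The libraries with no TPL held 4039 to 6173 contacts. In data simulated for TPL 1 h, 6.90% of 2-fold and 37.9% of 4-fold changes of a pair were called. The lack of calls thus does not show that the 2 series match. Without no TPL replicate 1, 1 block and 2 pairs were called, and without no TPL replicate 2, 3 pairs.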

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

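The tests of depth, bin division, shares summing to 100%, clone 1 alone and the untreated cells of another series were chosen only after the results were seen, as were the bounds that decide them and the tests of clone by Spt5; so were the splits kept within clones. The counts over other splits of the libraries were set before.

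Seen from IgG1, contacts at Emu rose and contacts at 60-130 kb fell after 72 h. The tables argue against depth as the cause of either part: with libraries thinned to 1 depth the changes were 2.18 (SE 0.0972, limma adjusted p = 2.1e-17) and -1.04, against 2.24 (SE 0.10) and -1.02. In contacts recovered without the bin division they were 1.95 (SE 0.152, adjusted p = 9.2e-12) and -1.01; the Emu change moved by more than 2 of its reported SE, which a stricter bound written first left undecided, so this argues against the division as the whole cause and not as part of it. Shares sum to 100%, but among contacts with no end at 10-50 kb or beyond 210 kb the stretch still held 38.7% at 0 h and 25.1% at 72 h (log2 -0.63, against -1.02), so the gains elsewhere may account for part of the fall. A move of contacts from the middle of the locus to its ends is a hypothesis found on the same data, and cell composition and batch were not tested.

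Across 24 blocks seen from IgG1, changes with Spt5 depletion ran against those of 72 h of activation (r = -0.929, rho = -0.889, 20 of 24 blocks opposite in sign). Of 100 splits of the 9 libraries, 3 gave a correlation as negative, the real one included, the lowest other being -0.957; with the groups of each clone kept in size 3 of 60 did, a share not under 0.05, so chance is not excluded. The slope of the Spt5 change on the activation change was -0.516 (SE 0.0877), in recovered contacts without the bin division -0.489 (SE 0.0704) and in clone 1 alone -0.417 (SE 0.129, 95% interval -0.749 to -0.0849, the spread taken over both clones), which argues against the division and against clone 2 as the whole cause. The depth and clone tests first planned here were replaced after the results were seen, and the slopes came last. A return toward the map of resting cells may follow Spt5 loss, but fewer activated cells could give the same and were not tested. The activation time of the controls is not given. Titles name AIDKO cells in the activation series and not in the Spt5 series, so these sets may also differ in AID. Their titles also name the IgG1 capture differently. What these differences do to the comparison was not tested.

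Contacts of Emu with IgG1 were higher after 1 h of TPL, and the libraries without TPL had the lowest mean depth (4039 to 6173 contacts, against 5317 to 13698 at 1 h). Thinned to 1 depth the change was 0.98 (SE 0.193, limma adjusted p = 0.0017), against 1.13 (SE 0.175), and against the untreated 72 h libraries of the activation series it was 0.84 (SE 0.166, adjusted p = 0.0075), which argues against depth and against low controls as the whole cause. In contacts recovered without the bin division it was 0.77 (SE 0.214, adjusted p = 0.014). That is a fall of more than 2 of the reported SE, undecided by the stricter bound written first. Recovery was less certain in the libraries without TPL (70.2% to 83.9% of diagonal values whole) than at 1 h (89.7% to 91.7%). The division may therefore account for part of the change. An effect of TPL is a hypothesis that remains open, and batch was not tested. In this series only the titles of the libraries without TPL end in _2. If that mark stands for a batch, it cannot be told apart from treatment within the series.

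In the Spt5 series seen from IgG1, 1 control, clone 1 replicate 3, lay far above the other 3 at 70-80 kb, at 2.41% of ends, and 1 of the 5 depleted libraries lay far below the others within 10-20 kb, at 0.432% of contacts. These were 2 of 70 groups of values examined this way, where chance gives about 1 in 20.

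The change from 0 to 72 h differed between the clones of the IgG1 capture in tests of the difference itself. Clone 2 minus clone 1 was 0.75 at 70-80 kb (limma adjusted p = 0.0499), 1.42 for pairs within 70-80 kb (adjusted p = 0.0053) and 2.22 for pairs of 220-230 kb with the last block (adjusted p = 0.0052). Limma called 1 block and 2 pairs, with 6 and 28 at unadjusted p under 0.05 and 0 and 0 by voom. Called blocks were 0 without 0 h clone 1 replicate 2, 0 h clone 2 replicate 1, 0 h clone 2 replicate 2, 72 h clone 1 replicate 2, 72 h clone 1 replicate 3 or 72 h clone 2 replicate 2; 2 without 0 h clone 1 replicate 1 or 72 h clone 2 replicate 1; 3 without 72 h clone 1 replicate 1. Called pairs were 0 without 0 h clone 1 replicate 2; 5 without 0 h clone 1 replicate 1.

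The change with Spt5 depletion also differed between the clones. Clone 2 minus clone 1 was -1.24 within 20-30 kb (limma adjusted p = 0.0084), -0.50 within 140-150 kb (adjusted p = 0.019) and -0.88 within the hs4 window (adjusted p = 0.016). Limma called 0 blocks and 2 pairs, with 2 and 37 at unadjusted p under 0.05 and 1 and 2 by voom. Called blocks were 3 without control clone 1 replicate 1. Called pairs were 0 without control clone 2 replicate 1; 1 without control clone 2 replicate 2, depleted clone 1 replicate 3, depleted clone 2 replicate 2 or depleted clone 2 replicate 3; 5 without control clone 1 replicate 1; 23 without depleted clone 1 replicate 4. By the median of ratios, where the median pair shifted by -0.88, limma called 15 pairs, all 15 lower in clone 2.

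Of 100 splits of the 9 Spt5 libraries seen from IgG1, 2 called as many blocks as the real 11 (highest other 11) and 2 as many pairs as the real 25 (highest other 29), the real one included, each a share under 0.05. That draw let the clones mix. With the groups of each clone kept in size, 1 and 1 of 60 splits did (highest other 8 and 23). Both are shares under 0.05 if the 9 libraries are separate samples. These splits came after the results were seen and left chance open for the correlation above. They bear on the 2 counts alone and do not exclude chance for the change as a whole. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. Where limma called 0 blocks and 0 pairs, all 10 of 10 splits gave as many by construction, and the highest other counts were 0 and 1 for Emu 72 against 48 h, 1 and 2 for hs4 72 against 48 h, 0 and 0 for IgG1 72 against 48 h, 0 and 2 for TPL 3 h, 0 and 0 for TPL 3 against 1 h and 1 and 1 for the untreated cells of 2 series. For TPL 1 h the real counts were 0 blocks (highest other 1) and 2 pairs (highest other 0), the latter reached by 1 of 10 splits. For IgG3 they were 1 block and 1 pair (highest other 0 and 0), each reached by 1 of 10 splits.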

How the results depend on the processing

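Results by a pseudocount of 10, the median of ratios, voom, thinning and recovered contacts, and those for clone by time, clone by Spt5 and the untreated cells of 2 series, come from tests chosen only after the data were seen. For the counts of called blocks and pairs, 80 values under an alternative lay beyond 1.5 times the reported count and the rest within it; with 1 library left out, 72 did and 150 did not. For named regions and elements, 1464 values kept direction and side of the threshold, 19 gained a call, 8 changed sign and the rest lost a call; with 1 library left out these were 893 kept, 5 gained, 6 changed in sign and the rest lost. For the crossing share, 57 kept and 11 turned. The TMM and DESeq2 scalings, chosen before the data were examined, were not run, because the values are a scaled signal.

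With the replicate number as a replicate block, limma called 6 for Emu 48 h against 0 h blocks (from 12), 5 for Emu 48 h against 0 h pairs (from 15), 1 for IgG1 72 h against 48 h pairs (from 0) and 3 for IgG1 Spt5 pairs (from 25). There were also 1 for IgG2a Spt5 pairs (from 2), 1 for Emu TPL 1 h pairs (from 2), 3 for IgG3 LPS blocks (from 1) and 2 for IgG3 LPS pairs (from 1). There were also 1 for untreated 72 h pairs (from 0). By voom, the counts were 10 for Emu 72 h against 0 h blocks (from 5), 4 for Emu 72 h against 48 h blocks (from 0), 4 for Emu 72 h against 0 h pairs (from 18) and 1 for Emu 72 h against 48 h pairs (from 0). There were also 1 for hs4 72 h against 48 h blocks (from 0), 21 for hs4 48 h against 0 h pairs (from 8), 23 for hs4 72 h against 0 h pairs (from 7) and 1 for hs4 72 h against 48 h pairs (from 0). There were also 4 for IgG1 72 h against 48 h blocks (from 0), 2 for IgG2a Spt5 blocks (from 0), 1 for IgG2a Spt5 pairs (from 2) and 6 for Emu TPL 1 h blocks (from 0). There were also 1 for Emu TPL 3 h blocks (from 0), 4 for Emu TPL 1 h pairs (from 2), 3 for Emu TPL 3 h against 1 h pairs (from 0) and 3 for IgG3 LPS blocks (from 1). There were also 3 for IgG3 LPS pairs (from 1), 0 for clone by time blocks (from 1), 0 for clone by time pairs (from 2) and 1 for clone by Spt5 blocks (from 0). There were also 2 for untreated 72 h blocks (from 0) and 1 for untreated 72 h pairs (from 0). Thinned, limma called 6 for Emu 48 h against 0 h blocks (from 12), 9 for Emu 48 h against 0 h pairs (from 15), 1 for IgG2a Spt5 pairs (from 2) and 1 for Emu TPL 1 h pairs (from 2). There were also 0 for IgG3 LPS blocks (from 1) and 0 for IgG3 LPS pairs (from 1). Without contacts near the viewpoint, limma called 11 for Emu 72 h against 0 h pairs (from 18), 2 for IgG1 72 h against 48 h blocks (from 0), 0 for IgG2a Spt5 pairs (from 2) and 1 for Emu TPL 1 h pairs (from 2). There were also 0 for IgG3 LPS blocks (from 1). In 20 kb blocks, limma called 23 for Emu 48 h against 0 h pairs (from 15), 8 for Emu 72 h against 0 h pairs (from 18), 14 for hs4 48 h against 0 h pairs (from 8) and 16 for hs4 72 h against 0 h pairs (from 7). There were also 47 for IgG1 48 h against 0 h pairs, 46 for IgG1 72 h against 0 h pairs, 1 for IgG1 72 h against 48 h pairs (from 0) and 16 for IgG1 Spt5 pairs (from 25). There were also 12 for IgG2a Spt5 pairs (from 2), 1 for Emu TPL 1 h pairs (from 2), 1 for Emu TPL 3 h pairs (from 0) and 1 for Emu TPL 3 h against 1 h pairs (from 0). In 5 kb blocks, limma called 16 for hs4 48 h against 0 h blocks (from 9), 31 for IgG1 48 h against 0 h blocks (from 17), 32 for IgG1 72 h against 0 h blocks (from 17) and 1 for IgG1 72 h against 48 h blocks (from 0). There were also 23 for IgG1 Spt5 blocks (from 11), 4 for Emu TPL 1 h blocks (from 0) and 0 for IgG3 LPS blocks (from 1). By the median of ratios, limma called 1 for IgG1 72 h against 48 h blocks (from 0), 13 for IgG1 Spt5 pairs (from 25), 1 for IgG2a Spt5 pairs (from 2) and 2 for Emu TPL 1 h blocks (from 0). There were also 1 for Emu TPL 1 h pairs (from 2), 1 for Emu TPL 3 h pairs (from 0), 3 for clone by time blocks (from 1) and 15 for clone by Spt5 pairs (from 2). With clones apart, limma called 3 for IgG1 72 h against 48 h blocks (from 0). In clone 2, limma called 67 for IgG1 48 h against 0 h pairs and 75 for IgG1 Spt5 pairs (from 25). In clone 1, limma called 0 for IgG1 Spt5 blocks (from 11) and 3 for IgG1 Spt5 pairs (from 25). Without a filter, limma called 13 for IgG1 Spt5 pairs (from 25), 1 for IgG2a Spt5 pairs (from 2) and 0 for IgG3 LPS pairs (from 1). With a pseudocount of 10, limma called 4 for IgG2a Spt5 pairs (from 2), 0 for IgG3 LPS pairs (from 1) and 0 for clone by time blocks (from 1). Replicate numbers showed little pairing of the libraries (mean correlations -0.0830 to 0.133), in a check that few libraries per group limit. Counts in 20 kb and 5 kb blocks also differ because fewer or more features are tested; otherwise the cause was not tested.

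Signs turned by voom for Emu 72 h against 48 h IgG1 with hs4 (0.42 to -0.029) and hs4 48 h against 0 h Emu with IgG1 (-0.39 to 0.33). Signs turned by the median of ratios for IgG1 Spt5 Emu with hs4 (0.21 to -0.10) and IgG3 LPS IgG1 with hs4 (-0.0041 to 0.12). Signs turned in clone 1 for IgG1 Spt5 Emu with hs4 (0.21 to -0.88), IgG1 Spt5 hs4 with hs4 (-0.42 to 0.059) and IgG1 Spt5 crossing (2.15 to -0.58). Signs turned without contacts near the viewpoint for IgG3 LPS IgG1 with hs4 (-0.0041 to 0.10). Signs turned with a pseudocount of 10 for IgG3 LPS IgG1 with hs4 (-0.0041 to 0.0039). Signs turned without pairs under 20 kb apart for Emu 48 h against 0 h crossing (-3.49 to 8.13), Emu 72 h against 0 h crossing (-2.7 to 2.37), Emu 72 h against 48 h crossing (0.795 to -5.76), hs4 72 h against 48 h crossing (1.78 to -2.14), IgG1 72 h against 48 h crossing (0.886 to -2.1) and Emu TPL 3 h against 1 h crossing (0.904 to -1.24). Signs turned in recovered contacts for Emu 72 h against 48 h crossing (0.795 to -0.0174), Emu TPL 1 h crossing (1.56 to -1.4) and Emu TPL 3 h crossing (2.47 to -0.0229). Signs turned in clone 2 for IgG1 72 h against 48 h crossing (0.886 to -0.159). The cause was not tested.

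Leaving out each library in turn gave 6 to 13 for Emu 48 h against 0 h blocks, 0 to 1 for Emu 72 h against 48 h blocks, 2 to 30 for Emu 48 h against 0 h pairs, 5 to 27 for Emu 72 h against 0 h pairs and 5 to 11 for hs4 48 h against 0 h blocks. It gave 0 to 1 for hs4 72 h against 48 h blocks, 4 to 12 for hs4 48 h against 0 h pairs, 4 to 9 for hs4 72 h against 0 h pairs, 0 to 2 for IgG1 72 h against 48 h blocks and 69 to 1.0e02 for IgG1 48 h against 0 h pairs (never above the reported count). It gave 0 to 2 for IgG1 72 h against 48 h pairs, 8 to 50 for IgG1 Spt5 pairs, 0 to 17 for IgG2a Spt5 pairs, 0 to 5 for Emu TPL 1 h blocks and 0 to 5 for Emu TPL 1 h pairs. It gave 0 to 1 for IgG3 LPS blocks, 0 to 2 for IgG3 LPS pairs, 0 to 3 for clone by time blocks, 0 to 5 for clone by time pairs and 0 to 3 for clone by Spt5 blocks. It gave 0 to 23 for clone by Spt5 pairs, 0 to 1 for untreated 72 h blocks, 0 to 3 for untreated 72 h pairs, -0.73 to 0.13 for hs4 48 h against 0 h Emu with IgG1 and -0.43 to 0.65 for IgG1 Spt5 Emu with hs4. It gave -0.46 to 0.055 for Emu TPL 3 h against 1 h IgG1 with hs4, -0.51 to 0.42 for IgG3 LPS IgG1 with hs4, -0.0372 to 1.89 for Emu 72 h against 48 h crossing, 1.71 to 2.58 for IgG1 Spt5 crossing and -0.815 to 2.42 for IgG3 LPS crossing. A lone sample left at 0 h, or in a control group, is assumed to vary like the other groups.

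Some calls were gained: by voom the hs4 site passed for TPL 1 h (log2 0.41, adjusted p = 0.0032) and for IgG3 (log2 0.59, adjusted p = 3.9e-05). For IgG3 it also passed with a replicate block (log2 0.61, adjusted p = 0.045) and without contacts near the viewpoint (log2 0.74, adjusted p = 0.014).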
